A study of Homo sapiens with 6 samples.

How the data were processed

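The deposited table holds 1 value per gene for 58735 genes in 6 libraries of C4-2B MDVR cells. The values were read as FPKM, as the authors deposited them: each value multiplied by the exon length of its gene fell on whole multiples of one step per library (within 0.05 fragments), and the column sums differed between libraries. The submitters' processing notes name HISAT for alignment and Cufflinks for quantification, without versions, and the genome build is not given in the sources used here. Whether reads were counted by strand is also not given in the sources used here, so values of genes that overlap are uncertain. Reads of genes with close paralogs or pseudogenes may be shared, which makes their values uncertain too. Both limits hold also where they are not repeated at the gene. Gene identifiers all matched GENCODE 29, with 0 unmapped, and 58207 were found in the current table of gene names. This is an own match, and it places ATF3 (ENSG00000162772) on GRCh38 chromosome 1 at 212565334 to 212620777, HSPA5 (ENSG00000044574) on chromosome 9 at 125234853 to 125241330, CDKN1A (ENSG00000124762) on chromosome 6 at 36676460 to 36687339 and FKBP5 (ENSG00000096060) on chromosome 6 at 35573585 to 35728583. Fragments per gene were recovered from the same step. The deposited FPKM follow median-of-ratios size factors rather than total fragments, so rescaling by median of ratios moves almost nothing.

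Values were analysed as log2 of FPKM plus 1. Genes with mean FPKM of 1 or more over the 6 libraries were kept (12960), and 27414 genes were 0 in every library. The enzalutamide dose is labelled (20 uM) on the single-agent library and not on the combinations; an equal dose was assumed there, and the additive, interaction and combination results depend on it. Differences between 2 libraries have no replicate check and are counted at log2 1 or more in either direction. Tests used limma 3.58.1 in R 4.3.3 with an intensity trend, two-sided, with p-values adjusted by the Benjamini-Hochberg method at 0.05. The additive model holds PTUPB as 3 levels plus enzalutamide, and the interaction model adds enzalutamide by linear PTUPB dose. The additive model assumes the enzalutamide effect to be equal at each dose, and p-values measure departures from that. It has 2 residual degrees of freedom, and fewer with 1 library left out. A call lost in such a fit does not show that the change rests on that library. The layout, this model, the level filter and the lists were chosen before the data were examined, as were the naming rule and most alternatives; limma-voom and scaling by total fragments were added later. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Recovery of known changes and false calls were tested on simulated data. In each of 5 runs, 200 of 12960 genes were changed for enzalutamide, in equal parts by log2 1 and log2 2. Another 200 were changed for 20 uM PTUPB.

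The 36 fixed lists cover androgen-induced and androgen-repressed genes, steroid receptors with cofactors, G1/S and G2/M cell cycle, ATF4 amino acid response, endoplasmic reticulum chaperones and unfolded protein response, cholesterol synthesis, LXR and cholesterol export, fatty acid synthesis, PPAR and fatty acid oxidation, arachidonic acid and prostaglandins, steroid metabolism, NRF2, AHR and xenobiotics, p53 targets, apoptosis, NF-kB, interferon, MYC and ribosome biogenesis, hypoxia and glycolysis, nuclear oxidative phosphorylation, mitochondrially encoded mRNAs, lysosome and autophagy, heat shock, immediate early genes, epithelial-mesenchymal transition, WNT targets, luminal identity, neuroendocrine genes, replication-dependent histones, housekeeping genes, and markers of basal epithelium, stroma, blood and endothelium. Lists were written from general knowledge, and some genes sit in more than 1 list, for example LDHA, MYC and SREBF1. The median of a list was placed among 10000 random lists matched on expression in 20 bins, and lists among the lowest or highest 2.5% stand apart; 31 lists had the 5 tested members required. Members of a list are co-regulated, so the percentile describes position and is not a test. Adjustment over a list alone was made within each list, with no correction across the 36 lists. A gene in more than 1 list is counted in each.

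Genes were named by rule: the 8 largest effects per direction among genes passing with one sign in every matched pair, filled by the largest effects of one sign where fewer pass; up to 4 genes per list with the largest effects; a fixed set (among them KLK3, FKBP5, TMPRSS2, NR3C1, EPHX2, PTGS2, AKR1C3, MKI67 and MYC); up to 5 per direction for the combination; and 5 for the interaction. Other named genes, such as CHAC1, ASNS, STEAP1, KRT19, MDM2 and CAMKK2, were chosen from the fixed lists after values were seen. Counting error alone is covered by any floor on low counts, and a fold is given only where both libraries hold more than 3 fragments. Some genes that the rule selects are not reported here. Splice variants, protein levels and cell numbers were not analysed here.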

Results

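C4-2B MDVR is an enzalutamide-resistant derivative of the human prostate cancer line C4-2B. The cells were treated for 2 days with enzalutamide, an antiandrogen, with PTUPB, a dual inhibitor of cyclooxygenase-2 and soluble epoxide hydrolase, or with both. The 6 libraries form a complete layout of PTUPB at 0, 10 or 20 uM without and with enzalutamide, at 1 library per group. Depth in fragments, recovered from the deposited FPKM, was 27337933 in control, 29450436 with enzalutamide, 28848961 and 22368705 with PTUPB at 10 and 20 uM, and 25627945 and 20156523 with enzalutamide added to these doses. In the same order, 12936, 12709, 13266, 12608, 13346 and 12285 genes had FPKM of 1 or more. The 12960 genes with mean FPKM of 1 or more were analysed. A difference between 2 libraries has no replicate check, so such pairs are given as values only. Tests come from limma over all 6 libraries, and their p-values measure departures from additivity, not replicate spread.

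With enzalutamide alone many androgen-induced genes were lower. FKBP5, which encodes a co-chaperone of steroid receptors, was 5.70-fold lower (35.4 to 6.21 FPKM) and SLC45A3, a prostate-restricted transporter gene, was 4.66-fold lower (128 to 27.5). C1orf116 was 2.75-fold, TMPRSS2 1.89-fold, and KLK3, which encodes prostate-specific antigen, 1.86-fold lower. KLK2 was 3.66-fold lower, but it and KLK3 are close paralogs and reads may be shared between them. Of 30 androgen-induced genes, 9 were lower by log2 1 or more and 0 were higher (median -0.81, or -1.25 after TPM; percentile 0 of 10000 expression-matched random lists). Androgen-repressed genes lay on the opposite side: 2 of 6 were higher by that margin (median 0.89, percentile 100), among them the opioid receptor gene OPRK1 (6.23-fold, 0.496 to 3.08 FPKM). UGT2B15, whose product inactivates androgens, was 2.29-fold higher, with the same uncertainty over shared reads within the UGT2B family. The largest difference among the named genes was in ST6GALNAC1, a sialyltransferase gene, 23.3-fold lower (22.2 to 0.955 FPKM). PLA2G2A, a secreted phospholipase that releases arachidonic acid, was 4.53-fold higher (6.47 to 29.3 FPKM).

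Mitochondrial and glycolysis genes also differed with enzalutamide alone. All 13 mitochondrially encoded mRNAs were higher by log2 1 or more (median 1.16, percentile 100; 0.73 after TPM), for example MT-CO1 at 23260 against 9808 FPKM. Of 27 hypoxia and glycolysis genes, 2 were lower by that margin (median -0.37, percentile 0; -0.80 after TPM); the lactate dehydrogenase gene LDHA was 1.93-fold and the phosphoglycerate kinase gene PGK1 2.07-fold lower. Reads of LDHA, PGK1 and the mitochondrial mRNAs may be shared with pseudogenes. Among ATF4 amino acid response genes (median 0.46, percentile 100; 0.05 after TPM), FGF21 was 4.98-fold, CHAC1 1.95-fold and DDIT4 1.69-fold higher. G2/M genes (median -0.35), G1/S genes (-0.22), heat shock genes (-0.29) and MYC and ribosome biogenesis genes (-0.19) all lay at percentile 0, and at -0.79, -0.65, -0.72 and -0.62 after TPM. The NF-kB list (-0.23, percentile 1.58; -0.67 after TPM) and luminal identity list (-0.19, percentile 0.02; -0.62 after TPM) were also low. Lysosome genes (0.29, percentile 99.77) and interferon genes (0.33, percentile 99.18) were high. After rescaling to TPM the medians were -0.11 and 0.02, still above the median of all genes of -0.41 in that scaling. Across all genes 170 were higher and 178 lower by log2 1 or more (48.9% higher). Rescaling to TPM moved the median of all genes by -0.41 and gave 140 higher and 652 lower (17.7%), and scaling by total fragments moved it by -0.16 and gave 33.2% higher.

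In the additive model over the matched pairs at 0, 10 and 20 uM PTUPB, androgen-induced genes had a median enzalutamide effect of -0.54 (percentile 0; -0.815 after TPM), from pair medians of -0.81, -0.92 and -0.10 at the 3 doses, with C1orf116 at -1.35 (SE 0.13, adjusted p 0.48), SLC45A3 at -1.59 (SE 0.46) and FKBP5 at -1.26 (SE 0.43, adjusted p 0.92). Among other genes, large values of one sign in every pair were those of ST6GALNAC1 at -2.42 (SE 0.63, adjusted p 0.92), the lipase gene PNLIPRP3 at -1.53 (SE 0.27, adjusted p 0.82), PLA2G2A at 1.22 (SE 0.28, adjusted p 0.92), FGF21 at 1.07 (SE 0.27), KCNK15-AS1 at 1.16 (SE 0.24) and TMEM59L at 1.06 (SE 0.18, adjusted p 0.81). FTH1 was at 1.08, but it has many processed copies and its reads are uncertain, as are those of the antisense gene KCNK15-AS1. The immunoglobulin pseudogene IGHVII-46-1, also in this set, held at most 7 fragments in any library. No gene passed by limma (0 of 12960), with 626 at unadjusted p under 0.05; limma-voom gave 1 gene and 679. After rescaling to TPM, 2 genes rose and 7 fell, with the median effect of all genes at -0.23 (0.01 as deposited). Adjusted over the list alone by limma, with no correction across lists, 6 androgen-induced genes fell, among them C1orf116 (p 0.0022), CAMKK2 (0.023) and TRPM8 (0.024). Adjusted over the list alone, DDIT4 (0.041) and ATF3 (0.042) rose in the ATF4 list, ELOVL7 (0.036) fell in the fatty acid synthesis list and ATF3 (0.033) rose in the immediate early list, with 0 in every other list.

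Single-library enzalutamide differences were only weakly related between PTUPB doses, though the interaction test called no gene. Their log2 ratios across genes correlated at 0.227 (Pearson) and 0.248 (Spearman) between 0 and 10 uM PTUPB, and at -0.034 and -0.044 between 0 and 20 uM; genes are not independent replicates. Of genes at log2 1 or more in both pairs, 67.2% shared direction in the former case and 53.3% in the latter. At all 3 doses 4 genes were higher and 5 lower by that margin, against a mean of 0.194 in 1000 shuffles of the genes, which do not allow for low-count genes swinging in every pair. The higher ones were the small RNA genes SNORD104, MIR200B, RNU6-118P and MIR4512, with at most 45 fragments in any library. C1orf116 and PNLIPRP3 were lower at every dose, as were MIR4766, RPL36AP30 and IGHVII-46-1, each with at most 32 fragments. In 12960 simulated genes of this layout with 200 changed for enzalutamide, its test recovered 93.6% of log2 1 changes at dispersion 0.01 and 41.6% at 0.05, and 98.6% and 98.8% of log2 2 changes. These dispersions are assumed and were not measured here, and fitted effects beyond log2 2 such as that of ST6GALNAC1 were not called, so the absence of calls does not rule out effects of any size. Of the calls of the simulated enzalutamide test, 12.4% and 10% were false at these dispersions, a share above the 0.05 that the adjustment aims at. Simulated effects were equal at every PTUPB dose, unlike the weakly related differences here, so these rates may not carry over.

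PTUPB at 10 uM alone gave metabolic differences in the same direction as enzalutamide alone, with smaller differences in androgen-induced genes. FASN, the fatty acid synthase gene, was 2.78-fold lower (350 to 126 FPKM), PGK1 2.53-fold lower and FKBP5 2.54-fold lower, whereas SLC45A3 stood at 125 against 128 FPKM. Of 13 mitochondrially encoded mRNAs, 8 were higher by log2 1 or more (median 1.07, percentile 100), and 3 of 27 hypoxia and glycolysis genes were lower (median -0.55, percentile 0; -0.90 after TPM). Endoplasmic reticulum chaperone genes had a median of 0.46 (percentile 100; 0.17 after TPM), with HSPA5 1.49-fold higher. The androgen-induced median was -0.27 (percentile 0), and the medians of G2/M and G1/S genes were -0.41 and -0.22; after TPM these were -0.60, -0.73 and -0.54. ATF4 response (0.23), lysosome (0.20) and interferon genes (0.28) were high as deposited. After rescaling to TPM they stood at -0.08, -0.10 and -0.02, still above the median of all genes of -0.33 in that scaling. Across genes 210 were higher and 100 lower (67.7% higher), with a median of all genes of -0.03. TPM put this median at -0.33 and gave 227 and 342 (39.9%), and total fragments put it at -0.11. These differences and those of enzalutamide alone share the same control library, so any peculiarity of that library enters both.

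In the additive model at 10 uM no gene passed by limma (0 of 12960; 480 at unadjusted p under 0.05), and limma-voom gave 0 and 560. List medians at percentile 0 were those of G2/M (-0.88), G1/S (-0.51), hypoxia and glycolysis (-0.48) and androgen-induced genes (-0.36), while the mitochondrially encoded (0.58), ATF4 (0.31) and endoplasmic reticulum lists (0.24; 0.12 after TPM) lay at percentile 100. For the mitochondrially encoded and endoplasmic reticulum lists this comes from the pair with control (1.07 and 0.46). With enzalutamide present their medians were 0.051 and -0.004 at 10 uM, the latter turning to 0.069 after TPM. G2/M and G1/S genes were lower with enzalutamide present (-1.372 and -0.786) than in the pair with control (-0.41 and -0.221). Housekeeping genes had an additive median of -0.298, close to that of the androgen-induced genes. Adjusted over the list alone, FASN fell (-1.24, p 0.028) in the fatty acid synthesis list and the count was 0 in all other lists. Log2 ratios of 10 uM PTUPB without and with enzalutamide correlated at 0.259 (Pearson) and 0.305 (Spearman) across genes, which are not independent replicates, and 66.1% of the 115 genes at log2 1 or more in both shared direction.

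PTUPB at 20 uM changed many genes: most endoplasmic reticulum, ATF4 and p53-linked genes rose, and MYC and most luminal, cell cycle and fatty acid synthesis genes fell. The largest riser was ATF3, a stress-induced transcription factor gene, from 4.62 to 205 FPKM without enzalutamide (44.3-fold) and from 7.32 to 450 with it (61.6-fold). HSPA5, which encodes the main endoplasmic reticulum chaperone, rose from 294 to 5919 and from 403 to 10392 FPKM and held the largest share of fragments of any gene in both 20 uM libraries. KLK3 fell from 105 to 0.648 FPKM (163-fold lower) and from 56.6 to 0.458 (124-fold lower), with reads uncertain among kallikrein paralogs, and MYC fell from 98.5 to 2.48 (39.7-fold lower) and from 94.5 to 3.27 (28.9-fold lower). Log2 ratios of 20 uM PTUPB without and with enzalutamide correlated at 0.745 (Pearson) and 0.726 (Spearman) across genes, which are not independent replicates. By log2 1 or more, 1227 genes were higher and 1640 lower at 20 uM without enzalutamide, and 1752 and 2047 with it. Of 1982 genes at that margin in both pairs, 97.4% shared direction; 790 were higher and 1141 lower in both, where independence would give 165.9 and 259.

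In the additive model, limma called 4426 genes for 20 uM PTUPB, 2064 rising and 2362 falling, with 6020 at unadjusted p under 0.05; limma-voom called 5001. The largest risers beside ATF3 (5.48, SE 0.21, adjusted p 0.0019) were GPNMB (4.57, SE 0.49, adjusted p 0.0042), HSPA5 (4.51, SE 0.28, adjusted p 0.0023), UPP1 (4.32, SE 0.21), DDIT3 (4.29, SE 0.20, adjusted p 0.0019), GADD45A (4.28, SE 0.26, adjusted p 0.0023), CHST1 (3.88, SE 0.28) and LCN2 (3.83, SE 0.60, adjusted p 0.0088). The largest fallers were KLK3 (-5.66, SE 0.46, adjusted p 0.0029), the mitochondrial transfer RNA gene MT-TR (-5.57, SE 0.30), MAB21L4 (-5.19, SE 0.16, adjusted p 0.0015), CRISP3 (-5.19, SE 0.24), SPDEF (-5.15, SE 0.42), MYC (-4.66, SE 0.20, adjusted p 0.0019), SPON2 (-4.65, SE 0.21) and LRRC26 (-4.58, SE 0.39). CRISP3 had 0 fragments in both 20 uM libraries. A fit with 1 library left out has fewer residual degrees of freedom, so a call lost there does not show dependence on that library. LCN2 did not pass without the control library (adjusted p 0.059) or without the enzalutamide library (adjusted p 0.059). Without the control 982 genes passed (366 rising, 616 falling), without the enzalutamide library 324 (115 and 209), and with no filter on low values 1201 of 31321. In 12960 simulated genes with 200 changed for 20 uM PTUPB, the test of that effect recovered 97.7% and 93.7% of log2 2 changes at dispersions 0.01 and 0.05. Of its calls 12.8% and 10.8% were false, a share above the 0.05 that the adjustment aims at. The simulated effects were exactly additive and far fewer genes changed than were called here. These rates therefore do not carry over to the 4426 calls, for which a false share held at 0.05 is not shown.

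**Figure D1:**
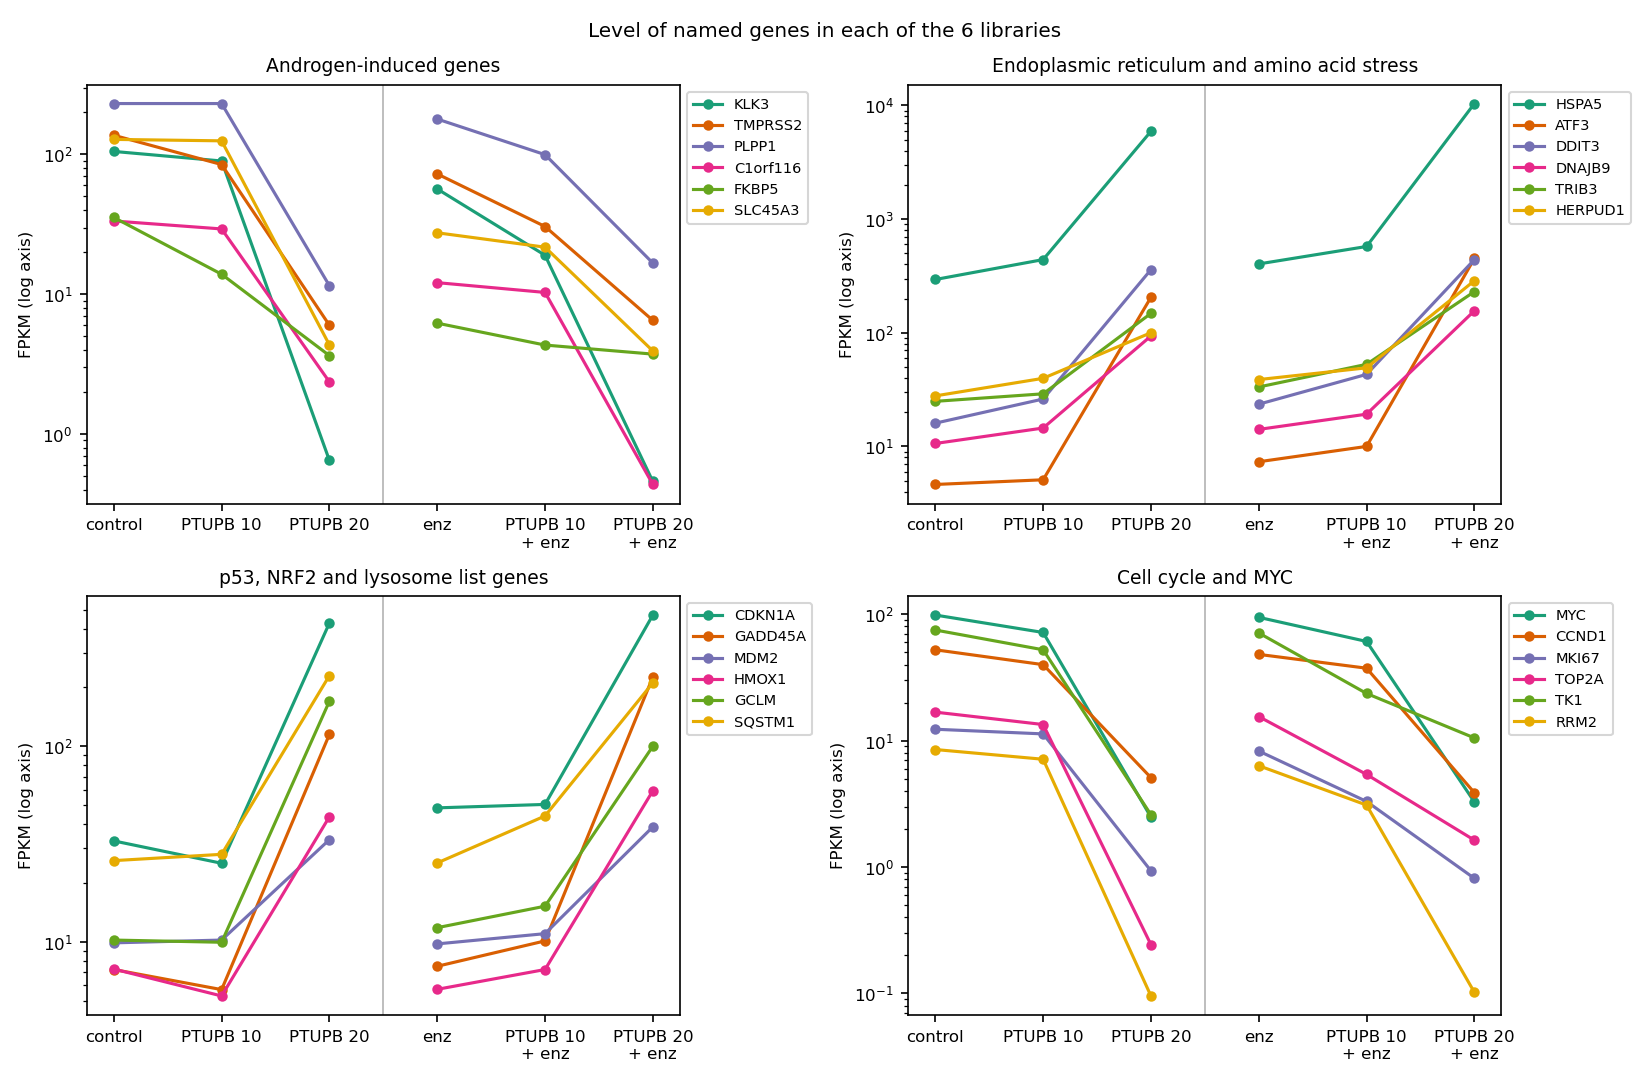
FPKM of androgen, stress, p53, NRF2, lysosome and cell cycle genes in the 6 libraries, ordered by PTUPB dose (uM) without enzalutamide (left of each panel) and with it (right).

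The higher dose was also tested directly against 10 uM, and p53 targets, androgen-induced, luminal and cell cycle genes differed between the doses. Limma called 4325 genes, 2132 higher and 2193 lower at 20 uM, with 6063 at unadjusted p under 0.05. After TPM 2764 were higher and 1905 lower, so the near-even balance depends on the scaling. Limma-voom called 5074. Of 23 p53 target genes 22 rose (median 1.67), of 30 androgen-induced genes 16 fell (median -1.29) and 4 rose, of 30 G2/M genes 16 fell (median -1.63), and of 18 fatty acid synthesis genes 11 fell (median -1.04). Luminal identity genes fell in 12 of 16 cases (median -2.89) and NRF2 genes rose in 11 of 19 (median 1.32). Adjusted over the list alone, 22 p53 targets rose, 19 androgen-induced genes fell and 6 rose, and 20 G2/M, 13 fatty acid synthesis and 12 luminal genes fell, and 13 NRF2 genes rose. Without 10 uM PTUPB 838 genes passed and the risers among p53 targets were 13 and among NRF2 genes 6, with falling G2/M genes at 4, fatty acid synthesis genes at 6 and androgen-induced genes at 11 (risers 2). Without 10 uM PTUPB plus enzalutamide 1139 passed, with 11 p53 targets rising, 5 fatty acid synthesis genes falling and 1 androgen-induced gene rising. The total was 2578 without control, 2581 without enzalutamide and 868 with no filter. Leaving out 20 uM PTUPB let 7 androgen-induced genes rise, and leaving out 20 uM PTUPB plus enzalutamide let 27 G2/M genes fall.

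Most endoplasmic reticulum stress and amino acid response genes rose at 20 uM PTUPB. Of 22 endoplasmic reticulum chaperone and unfolded protein response genes, 14 rose, 0 fell and 8 did not pass (median 1.05, percentile 100; 15 rose adjusted over the list alone). HSPA5 is joined by DNAJB9 (3.20, SE 0.19, adjusted p 0.0021; 8.82-fold and 11.1-fold without and with enzalutamide), HERPUD1 (2.33, SE 0.33, adjusted p 0.0071) and HYOU1 (1.95, SE 0.24). Of 31 ATF4 genes, 16 rose, 4 fell and 11 did not pass (median 1.02, percentile 100; 18 and 5 adjusted over the list alone). ATF3, DDIT3, the phosphatase regulator gene PPP1R15A (3.18, SE 0.21, adjusted p 0.0023) and TRIB3 (2.63, SE 0.20) rose, whereas SLC7A5 (-1.24), PSAT1 (-1.07), PSPH (-1.06) and ATF5 (-1.42), which serve amino acid uptake and serine synthesis or share the pathway, fell. DDIT3 encodes the pro-apoptotic factor CHOP and stood at 359 and 440 FPKM against 16 and 23.5. Without the control 4 endoplasmic reticulum genes rose, and 11 ATF4 genes rose and 0 fell; without enzalutamide the counts were 2, 6 and 1. Without 20 uM PTUPB plus enzalutamide 2 ATF4 genes fell. HYOU1 did not pass without control or without enzalutamide, nor HERPUD1 without enzalutamide. Of the 4 falling genes, SLC7A5, PSAT1 and PSPH did not pass without control or without enzalutamide, and ATF5 did not pass without control. SLC7A5 and PSAT1 also did not pass without the 20 uM combination, nor ATF5 without 20 uM PTUPB.

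The p53 target list was the most uniform riser. Of 23 genes 22 rose, 0 fell and TP53INP1 alone did not pass (0.05, SE 0.26, adjusted p 0.91); the list median was 1.58 (percentile 100), and 22 rose adjusted over the list alone. The cell cycle inhibitor gene CDKN1A rose from 32.8 to 427 FPKM (13.0-fold) without enzalutamide and from 48.4 to 469 (9.68-fold) with it (3.46, SE 0.26, adjusted p 0.0025). GADD45A, SESN2 (2.44, SE 0.26, adjusted p 0.0041) and PHLDA3 (2.38, SE 0.20) rose, and MDM2, which encodes the ubiquitin ligase of p53, rose by 1.77 (SE 0.17, adjusted p 0.0033). GADD45A, SESN2 and CDKN1A also respond to integrated stress signalling, so the list does not separate p53 from that input. Without control 10 targets rose and without enzalutamide 7; MDM2 did not pass without enzalutamide (adjusted p 0.058). Of 22 apoptosis genes 8 rose, 3 fell and 11 did not pass (median 0.28, percentile 90.2; 8 and 5 adjusted over the list alone). HRK, a BH3-only gene, rose by 2.53 (SE 0.24, adjusted p 0.0034), while BIRC5 (-3.10), BIK (-1.83) and BID (-1.45) fell. Without control 1 apoptosis gene rose and 2 fell, BIRC5 no longer passing (adjusted p 0.12); without enzalutamide 1 rose and 0 fell, with BIRC5 at 0.13, BIK at 0.057 and BID at 0.081.

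Most NRF2 and immediate early genes rose, and 8 of 25 lysosome and autophagy genes did. Of 19 NRF2 genes 11 rose, 1 fell and 7 did not pass (median 1.24, percentile 100; 13 and 2 adjusted over the list alone). By limma GCLM, a glutathione synthesis gene, rose by 3.46 (SE 0.33, adjusted p 0.0034) and HMOX1 by 2.80 (SE 0.23, adjusted p 0.0029). OSGIN1 rose by 2.23, and the peroxiredoxin gene PRDX1 fell by 1.94. FTH1 rose by 3.45 (SE 0.41, adjusted p 0.005), with the uncertainty over its processed copies, which PRDX1 shares. Of 25 lysosome and autophagy genes 8 rose, 1 fell and 16 did not pass (median 0.48, percentile 99.2; 8 and 2 adjusted over the list alone), led by GPNMB, the autophagy receptor gene SQSTM1 (3.05, SE 0.25, adjusted p 0.0029), MAP1LC3B (2.32, SE 0.17) and WIPI1 (2.11). Of 12 immediate early genes 7 rose and 1, MYC, fell, with 4 not passing (median 1.09, percentile 100; 8 and 2 adjusted over the list alone); ATF3, DUSP5 (2.11) and JUNB (1.98) rose most. Of 8 replication-dependent histone genes 4 rose, 0 fell and 4 did not pass (median 1.08, percentile 99.9; 6 rose adjusted over the list alone), led by H1-2 (2.38, SE 0.20, adjusted p 0.0029), with reads uncertain within the histone family. Without control 6 NRF2, 5 lysosome, 5 immediate early and 1 histone gene rose, and ATG9B, the lysosome faller (-0.83), did not pass; without enzalutamide 4, 3, 1 and 1 rose, and PRDX1 (adjusted p 0.079), FTH1 (0.058), WIPI1 (0.057), DUSP5 (0.073), JUNB (0.11) and ATG9B (0.21) did not pass. The immediate early fallers numbered 2 without 20 uM PTUPB. ATG9B also did not pass without 10 uM PTUPB (0.057) or 10 uM PTUPB plus enzalutamide (0.055).

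Interferon and NF-kB genes moved in both directions. The NF-kB pair medians were -0.1 at 20 uM PTUPB without enzalutamide and 0.546 with it, so the additive median of that list averages opposite signs. Of 14 interferon genes 5 rose, 1 fell and 8 did not pass (median 0.61, percentile 98.9; 6 and 1 adjusted over the list alone): IRF1 (1.95) and IRF7 (1.28) rose among others and BST2 (-2.22) fell. Of 8 NF-kB genes 3 rose, 2 fell and 3 did not pass, unchanged adjusted over the list alone (median 0.41, percentile 91.7); the non-canonical subunit gene RELB (2.24) and LIF (1.38) rose, while TNFAIP2 (-1.93) and SOD2 (-0.91) fell. Without enzalutamide 0 interferon genes changed, 0 NF-kB genes rose and 1 fell, RELB standing at adjusted p 0.058 and BST2 at 0.06. Without control 1 interferon gene rose and 1 NF-kB gene fell, IRF7 standing at 0.068. Without 10 uM PTUPB, or without 10 uM PTUPB plus enzalutamide, 3 interferon genes rose and 1 NF-kB gene fell; 2 interferon genes fell without 20 uM PTUPB. Leaving out 20 uM PTUPB gave 2 falling interferon genes. LIF did not pass without 20 uM PTUPB plus enzalutamide (adjusted p 0.071).

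The androgen-induced programme fell at 20 uM PTUPB. The pioneer factor gene FOXA1 fell by 3.78 (SE 0.30, adjusted p 0.0029; 11.3-fold and 24.2-fold lower in the pairs) and HOXB13 by 3.04 (SE 0.18, adjusted p 0.0021). Of 30 androgen-induced genes, 21 fell, 3 rose and 6 did not pass (median -1.71, percentile 0; 22 fell and 3 rose adjusted over the list alone). TMPRSS2 fell 22.9-fold and 11.2-fold in the pairs (-3.80, SE 0.37, adjusted p 0.0035), and PLPP1 fell by 3.78 (SE 0.40). FKBP5 fell by 1.79 (SE 0.53, adjusted p 0.047), while ERRFI1 (1.40), EAF2 (1.53) and ZBTB10 (1.26) rose. KLK2, subject to shared kallikrein reads, fell by 4.47 (SE 0.62, adjusted p 0.0067). Androgen-repressed genes did not rise: of 6, 4 fell, among them FOLH1 and UGT2B15 (both with close paralogs), and 2 did not pass (median -2.57, percentile 0; 4 fell adjusted over the list alone). Of 10 steroid receptor and cofactor genes, 5 fell, 1 rose and 4 did not pass (median -0.70, percentile 0.97; 5 fell and 2 rose adjusted over the list alone). NR3C1, which encodes the glucocorticoid receptor, was below the level analysed, at 0.0839 FPKM in control and 0.517 at 20 uM PTUPB.

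These androgen calls differ in whether they passed with 1 library left out, where the fit also has fewer residual degrees of freedom. In the pairs the androgen-induced median was -2.015 without enzalutamide and -1.387 with it. FOXA1, HOXB13, TMPRSS2, KLK3 and PLPP1 passed whichever library was left out. Without control 12 androgen-induced genes fell and 1 rose, and 3 cofactor genes fell; without enzalutamide 8 fell and 0 rose, and 3 cofactor genes fell. FKBP5 did not pass without control (adjusted p 0.25), enzalutamide (0.065) or 20 uM PTUPB (0.099). KLK2 (0.059) and UGT2B17 (0.06) did not pass without enzalutamide, nor did ERRFI1 (0.097); EAF2 and ZBTB10 did not pass without control (0.085 and 0.056) or enzalutamide (0.18 and 0.19). The risers numbered 5 without 20 uM PTUPB. Among cofactor genes NCOA1 (0.60) did not pass without control (0.25), enzalutamide (0.24), 20 uM PTUPB (0.064), 10 uM PTUPB (0.1) or 10 uM PTUPB plus enzalutamide (0.1), while without 20 uM PTUPB plus enzalutamide both it (0.034) and NCOA3 (0.029) rose.

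Luminal prostate identity fell with the androgen programme, and none of the few tested basal or neuroendocrine genes rose in its place. Of 16 luminal genes 12 fell, 1 rose and 3 did not pass (median -3.01, percentile 0; 12 and 1 adjusted over the list alone). The acid phosphatase gene ACP3 fell by 4.27 (SE 0.34) and the membrane antigen gene FOLH1, which encodes PSMA, by 2.83 (SE 0.30, adjusted p 0.0041), while STEAP1 (-3.36) and KRT19 (-2.62) also fell. CDH1 rose by 0.95 (SE 0.25, adjusted p 0.033), and KRT8, KRT18 and EPCAM did not pass (0.49, 0.48 and -0.20). Of 3 tested neuroendocrine genes DLL3 (-0.86, adjusted p 0.044) and ENO2 (-0.83, adjusted p 0.035) fell and ONECUT2 did not pass (0.03). Neither of the tested basal genes passed with all libraries (ITGA6 -0.52, ITGB4 -0.74). Of 11 epithelial-mesenchymal transition genes 4 fell, 2 rose and 5 did not pass (median -0.91, percentile 0.21; 7 and 2 adjusted over the list alone), with CLDN4 (-2.21), FN1 (-1.60), CLDN3 (-1.24) and SNAI1 (-1.16) falling. This list mixes epithelial genes, such as CLDN3 and CLDN4, with mesenchymal genes, such as FN1 and SNAI1. Its median and counts therefore give no direction of a transition. Among 3 stroma marker genes FBLN1 fell (-1.37, adjusted p 0.016), COL1A1 rose (0.96, adjusted p 0.016) and COL5A1 did not pass (-0.77); 0 blood and 0 endothelium marker genes were expressed at the level analysed. Of 5 WNT target genes 3 fell and 2 did not pass (median -1.41, percentile 0.41; 3 fell adjusted over the list alone), with the cyclin gene CCND1 falling from 52.3 to 5.09 FPKM and from 48.1 to 3.87 (-3.23, SE 0.17, adjusted p 0.0019).

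In these lineage lists CLDN4, CCND1, ACP3, FOLH1, STEAP1 and KRT19 passed whichever library was left out. Without control, and likewise without enzalutamide, 0 luminal genes rose, 1 epithelial-mesenchymal transition gene fell and 0 rose, and 0 neuroendocrine and 0 stroma genes passed. Without enzalutamide 1 WNT target fell. CDH1 did not pass without control (adjusted p 0.24), enzalutamide (0.13), 20 uM PTUPB (0.093) or 20 uM PTUPB plus enzalutamide (0.056). Without 20 uM PTUPB, DLL3 (0.11), FBLN1 (0.055) and SNAI1 (0.058) did not pass while 2 luminal genes rose and the basal gene ITGA6 fell (0.016). Without 20 uM PTUPB plus enzalutamide ENO2 (0.089) did not pass and ITGB4 fell (0.04). Without 10 uM PTUPB, or 10 uM PTUPB plus enzalutamide, ESRP1 (0.79), the other riser of the epithelial-mesenchymal list, stood at adjusted p 0.06.

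Most G2/M and G1/S genes fell at 20 uM, with fewer calls when the control or enzalutamide library was left out. In the pairs without and with enzalutamide the medians were -3.01 and -1.94 for G2/M genes. For G1/S genes they were -1.56 and -1.46, so both lists were lower in both pairs. Of 30 G2/M genes 29 fell, 0 rose and CDC20 alone did not pass (-2.37, SE 0.94), with a list median of -2.46 (percentile 0; 30 fell adjusted over the list alone). MKI67 fell from 12.3 to 0.932 FPKM (13.2-fold lower) and from 8.27 to 0.813 (10.2-fold lower; -2.57, SE 0.34, adjusted p 0.0063), and DLGAP5 (-3.75, SE 0.49), TOP2A (-3.24, SE 0.50), KIF20A (-3.11) and KIF2C (-2.81, SE 0.23, adjusted p 0.0029) fell. Of 30 G1/S genes 22 fell, 0 rose and 8 did not pass (median -1.47, percentile 0; 23 fell adjusted over the list alone), with the thymidine kinase gene TK1 (-3.53, SE 0.62), the ribonucleotide reductase gene RRM2 (-2.92, SE 0.27) and the helicase gene MCM4 (-2.50, SE 0.21, adjusted p 0.003) falling. MYC itself fell, but of 27 MYC and ribosome biogenesis genes only 5 fell, 2 rose and 20 did not pass (median -0.34, percentile 2.58; 4 and 1 adjusted over the list alone); NOP56 (-1.45) and BOP1 (-1.40) fell. Without control 9 G2/M, 9 G1/S and 1 MYC-list gene fell, and without enzalutamide 1, 4 and 1, with 0 MYC-list genes rising in each case. Without 20 uM PTUPB plus enzalutamide 11 MYC-list genes fell and 1 rose, and without 10 uM PTUPB or 10 uM PTUPB plus enzalutamide 1 rose. RRM2, MCM4, KIF2C and MYC passed in every case. MKI67 (adjusted p 0.068), DLGAP5 (0.062) and KIF20A (0.067) did not pass without enzalutamide, TOP2A (0.054 and 0.073) and TK1 (0.07 and 0.08) without control or enzalutamide, nor NOP56 (0.088 and 0.098) and BOP1 (0.2 and 0.093).

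Most fatty acid synthesis genes fell at 20 uM. Of 18 fatty acid synthesis genes 12 fell, 1 rose and 5 did not pass (median -1.27, percentile 0; 13 and 3 adjusted over the list alone). SREBF1, the transcriptional regulator of this branch, fell from 115 to 12.6 FPKM and from 124 to 9.48 (-3.33, SE 0.21, adjusted p 0.0023), FASN from 350 to 33.3 and from 212 to 26.3 (-3.16, SE 0.22, adjusted p 0.0023), FADS2 by 3.60 (SE 0.21) and ELOVL6 by 2.44. Of 23 cholesterol synthesis genes 6 fell, 0 rose and 17 did not pass (median -0.06, percentile 30.5; 5 fell adjusted over the list alone), among them TM7SF2 (-1.97, SE 0.18), LSS (-1.45) and EBP (-1.27). Of 7 LXR and cholesterol export genes 2 fell (SREBF1 and LPCAT3, -1.11), 1 rose (NR1H2, 0.74) and 4 did not pass (2 and 2 adjusted over the list alone), with a median of 0.02 (percentile 50.5) that turned to -0.04 when scaled by total fragments. Of 19 PPAR and fatty acid oxidation genes 6 fell, 1 rose and 12 did not pass (median -0.24, percentile 10.8; 7 and 2 adjusted over the list alone); CPT1A, needed for mitochondrial fatty acid import, fell (-2.22, SE 0.22) and PPARG rose (1.33, SE 0.25, adjusted p 0.014). Without control 1 cholesterol and 2 PPAR-list genes fell, and without enzalutamide 4 fatty acid, 0 cholesterol and 2 PPAR-list genes; the lone risers of the fatty acid list, ME1 (1.87), and of the PPAR list were lost in both cases. TM7SF2 did not pass without enzalutamide (adjusted p 0.053), LSS (0.076 and 0.11) and PPARG (0.11 and 0.073) without control or enzalutamide, and EBP without these (0.066 and 0.17) or 20 uM PTUPB (0.054). LPCAT3 and NR1H2 did not pass without control (0.063 and 0.14), enzalutamide (0.3 and 0.27), 10 uM PTUPB (0.054 and 0.072), 10 uM PTUPB plus enzalutamide (0.053 and 0.072) or 20 uM PTUPB plus enzalutamide (0.096 and 0.051). Without 20 uM PTUPB plus enzalutamide 3 fatty acid genes rose; without 20 uM PTUPB 4 cholesterol genes fell, 1 rose and 2 PPAR-list genes rose, the latter also without the 20 uM combination.

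The genes of the drug targets give little reading for cyclooxygenase-2. PTGS2, which encodes cyclooxygenase-2, had fragments only in 10 uM PTUPB plus enzalutamide (2 fragments, 0.0144 FPKM). EPHX2, which encodes soluble epoxide hydrolase, was expressed and fell at 20 uM, 2.75-fold lower without enzalutamide (8.97 to 3.26 FPKM) and 2.31-fold lower with it (-1.12, SE 0.16, adjusted p 0.0076). Of 20 arachidonic acid and prostaglandin genes 8 fell, 2 rose and 10 did not pass (median -0.45, percentile 2.46; 8 and 2 adjusted over the list alone), with PLA2G2A (-2.93, SE 0.34, adjusted p 0.0048), GGT1 (-2.55, SE 0.18) and ABCC4 (-2.71) falling and the hydroxylase gene CYP4F11 (2.15) rising. Of 12 steroid metabolism genes 7 fell, 1 rose and 4 did not pass (median -1.07, percentile 0.02; 7 and 1 adjusted over the list alone). UGT2B15 (-3.87, SE 0.33, adjusted p 0.003) and HSD3B7 (-1.99, SE 0.20) fell. AKR1C3, which makes potent androgens and prostaglandins, rose by 1.84 (SE 0.48, adjusted p 0.035), to 5.58 FPKM at 20 uM PTUPB and 1.64 with enzalutamide added, with reads uncertain among AKR1C paralogs, as they are for CYP4F11, GGT1 and GSTA1. Of 6 AHR and xenobiotic genes 2 fell, 1 rose and 3 did not pass (median -0.38, percentile 17.0; 2 and 2 adjusted over the list alone), GSTA1 (-3.28, SE 0.27) and CYP1B1 (-1.36) falling and TIPARP (1.63) rising. Without control 4 arachidonic acid, 3 steroid and 1 AHR-list gene fell, and without enzalutamide 2, 1 and 1, with 0 rising in each case. EPHX2 (adjusted p 0.077 and 0.09), CYP4F11 (0.075 and 0.064), CYP1B1 (0.14 and 0.22) and TIPARP (0.083 and 0.11) did not pass without control or enzalutamide, AKR1C3 without these (0.2 and 0.13) or 20 uM PTUPB (0.068), and ABCC4 (0.057) and HSD3B7 (0.051) without enzalutamide. Without 20 uM PTUPB 1 arachidonic acid gene rose, and without 20 uM PTUPB plus enzalutamide 2 AHR-list genes rose.

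Energy metabolism and housekeeping genes moved unevenly. Heat shock genes had pair medians of -0.838 at 20 uM PTUPB without enzalutamide and 0.099 with it, so their additive median averages opposite signs. Of 27 hypoxia and glycolysis genes 14 fell, 3 rose and 10 did not pass (median -0.80, percentile 0.01; 15 and 4 adjusted over the list alone): LDHA fell from 114 to 15 FPKM (-2.30, SE 0.31, adjusted p 0.0064) and the carbonic anhydrase genes CA12 (-3.08) and CA9 (-1.90) fell, while P4HA2 rose by 2.43. Of 24 nuclear oxidative phosphorylation genes 6 fell, 0 rose and 18 did not pass (median -0.21, percentile 7.75; 1 fell adjusted over the list alone), with NDUFB3 (-1.47), COX7A2 (-1.07) and NDUFA4 (-0.97) falling. Of 13 mitochondrially encoded mRNAs only MT-CO2 fell (-1.45, SE 0.43, adjusted p 0.047) and 12 did not pass (median -0.66, percentile 0.72; 0 adjusted over the list alone). Of 15 heat shock genes 3 fell, 1 rose and 11 did not pass (median -0.33, percentile 7.25; 3 and 1 adjusted over the list alone): HSPB1 (-2.49), HSPE1 (-1.92) and HSPA8 (-1.62) fell and HSPA4L rose (1.73), unlike the endoplasmic reticulum chaperones. Of 15 housekeeping genes 4 fell, 2 rose and 9 did not pass (median -0.09, percentile 26.9; 4 and 3 adjusted over the list alone); PGK1 (-1.39), HPRT1 (-1.18) and PPIA (-1.08) fell and ACTB did not pass (-0.09). LDHA, HSPE1, HSPA8, PGK1, HPRT1, PPIA, ACTB and MT-CO2 have pseudogenes or close paralogs, so their reads are uncertain.

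Calls in these energy lists were fewer without the control or enzalutamide library, where the fit also has fewer residual degrees of freedom. P4HA2 and CA12 passed whichever library was left out. In the pairs the hypoxia and glycolysis median was -1.05 without enzalutamide and -0.416 with it. Without control 2 hypoxia genes fell and 2 rose, 1 oxidative phosphorylation and 1 heat shock gene fell, and 0 housekeeping and 0 mitochondrially encoded genes passed. Without enzalutamide 1 hypoxia gene fell and 1 rose, and 0 passed in the other lists. LDHA stood at adjusted p 0.052 and 0.051, CA9 at 0.096 and 0.13, HSPB1 at 0.091 and 0.064, HSPA8 at 0.052 and 0.088, PGK1 at 0.15 and 0.073 and HPRT1 at 0.054 and 0.15 without control or enzalutamide. HSPE1 (0.055), HSPA4L (0.072) and NDUFB3 (0.1) did not pass without enzalutamide. MT-CO2 also did not pass without 20 uM PTUPB (0.4) or 20 uM PTUPB plus enzalutamide (0.5), while 3 mitochondrially encoded mRNAs fell without 10 uM PTUPB or 10 uM PTUPB plus enzalutamide. In the oxidative phosphorylation list 3 genes fell without either of those libraries or without 20 uM PTUPB plus enzalutamide; COX7A2 (0.054) and NDUFA4 (0.089) did not pass without the last, and NDUFA4 (0.054) without 20 uM PTUPB. In the heat shock list 4 genes rose without 20 uM PTUPB and 7 fell without 20 uM PTUPB plus enzalutamide. PPIA (0.052) did not pass without 20 uM PTUPB, which left 2 falling housekeeping genes, and in each case of 1 library left out at most 1 housekeeping gene rose.

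**Figure D2:**
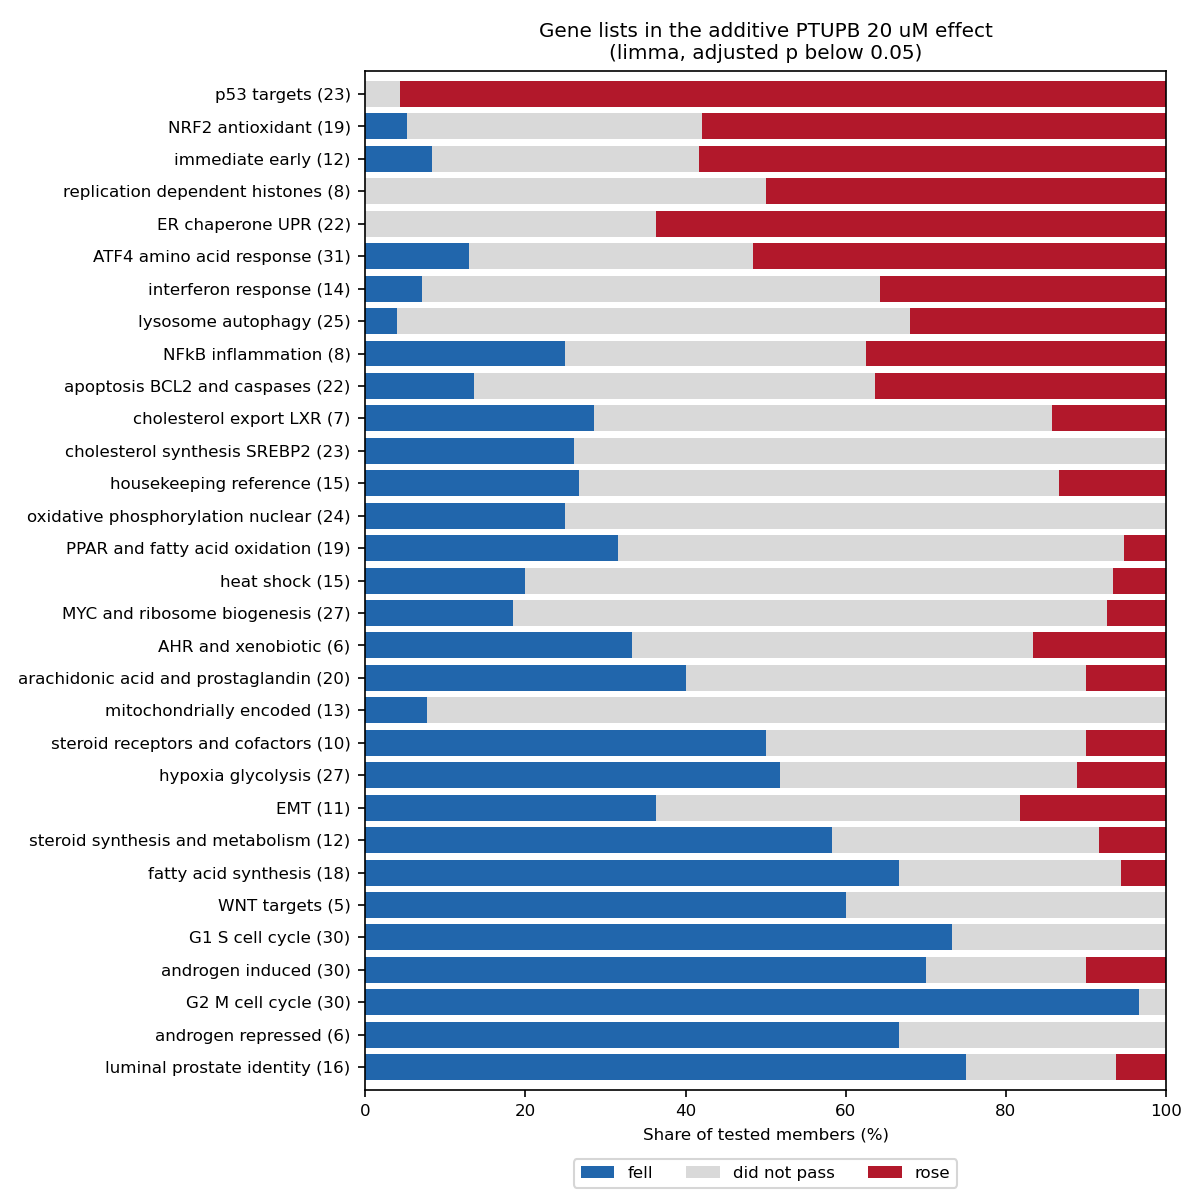
Share of tested members of each gene list that rose, fell or did not pass in the additive 20 uM PTUPB effect (limma, adjusted p below 0.05), with the number tested in brackets; the cholesterol export median changes sign when scaled by total fragments.

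G2/M genes were lower in 10 uM PTUPB plus enzalutamide than with either agent alone, and androgen-induced genes were lower mainly against 10 uM PTUPB. Against 10 uM PTUPB, KLK2 was 9.21-fold lower (shared kallikrein reads again), SLC45A3 5.78-fold (125 to 21.7 FPKM), KLK3 4.71-fold (89.7 to 19), FKBP5 3.21-fold and TMPRSS2 2.77-fold lower. Of 30 androgen-induced genes 15 were lower by log2 1 or more (median -0.92, percentile 0), compared with 9 for enzalutamide alone against control. Against enzalutamide alone 4 were lower by that margin (median -0.395, percentile 0). In that pair the housekeeping list (-0.371) and the nuclear oxidative phosphorylation list (-0.387) were about as low. G2/M genes had a median of -1.27 against 10 uM PTUPB and -1.37 against enzalutamide (percentile 0 in both), with 24 and 25 of 30 lower by log2 1 or more. KIF20A was 4.46-fold and 4.05-fold, CCNA2 3.81-fold and 3.28-fold and MKI67 3.41-fold and 2.51-fold lower in these pairs. G1/S genes had medians of -0.83 and -0.79. ATF4 genes were higher against 10 uM PTUPB (median 0.53, percentile 100) and against enzalutamide (0.36, percentile 100), for example ASNS 2.16-fold and 1.49-fold. Against control all 30 G2/M genes were lower by log2 1 or more (median -1.65), as were 18 of 30 androgen-induced genes (median -1.21), and 12 of 31 ATF4 genes were higher (median 0.79).

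Across all genes the 10 uM combination had 183 higher and 260 lower than 10 uM PTUPB, 290 higher and 204 lower than enzalutamide, and 351 higher and 335 lower than control (51.2% higher). At mean FPKM of at least 5 the balance against enzalutamide turned, with 52 higher and 96 lower. Against control, TPM put the median of all genes at -0.36, from -0.02 as deposited, and gave 334 higher and 990 lower (25.2%). These are differences between single libraries and carry no test.

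At 20 uM PTUPB, where androgen-induced genes were already low, their median with enzalutamide added was -0.10 against 20 uM PTUPB (percentile 1.19), and -0.417 after TPM or -0.269 by total fragments, with KLK3 at 0.458 against 0.648 FPKM, SLC45A3 at 3.93 against 4.34 and FKBP5 at 3.73 against 3.64. C1orf116 (5.42-fold) and FOXA1 (2.46-fold) were lower. Endoplasmic reticulum genes were higher (median 0.57, percentile 99.77; 0.26 after TPM and 0.36 by total fragments), with HERPUD1 2.86-fold and HSPA5 1.76-fold, and ATF3 was 2.20-fold and the transporter gene SLC3A2 2.59-fold higher. NRF2 genes (-0.40), fatty acid synthesis genes (-0.34) and histone genes (-0.48) were lower, at -0.73, -0.69 and -0.81 after TPM. G2/M genes were slightly higher (median 0.47, percentile 100; 8 of 30 by log2 1 or more), all from very low levels in 20 uM PTUPB; TOP2A stood at 1.63 against 0.243 FPKM but CCNA2 at 0.0974 against 0.393.

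Genes in which the 20 uM combination lay at least log2 1 beyond control, enzalutamide and 20 uM PTUPB numbered 256 higher and 131 lower; TPM gave 165 and 654 and total fragments 140 and 208. On the higher side stood ATF3 and the zinc transporter gene SLC30A2 (18.8 FPKM against 5.6 at 20 uM PTUPB, 0.486 with enzalutamide and 0.23 in control), with the small genes RNA5SP155, MIR4653 and RNU7-49P at 63, 30 and 33 fragments against at most 1, 15 and 7 elsewhere. On the lower side stood C1orf116, FOXA1 and STEAP2 (4.86 FPKM against 13.3 at 20 uM PTUPB), and the mitochondrial transfer RNA gene MT-TH with 0 fragments against 10. Across all genes 497 were higher and 376 lower than in 20 uM PTUPB (56.9% higher, median 0.04). TPM put the median at -0.24 and gave 22.5% higher, and total fragments put it at -0.12 and gave 35.1%. Against control 1813 were higher and 1945 lower (48.2%, median 0.02), with 28.6% higher after TPM (median -0.28) and 32.7% by total fragments (median -0.19).

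**Figure D3:**
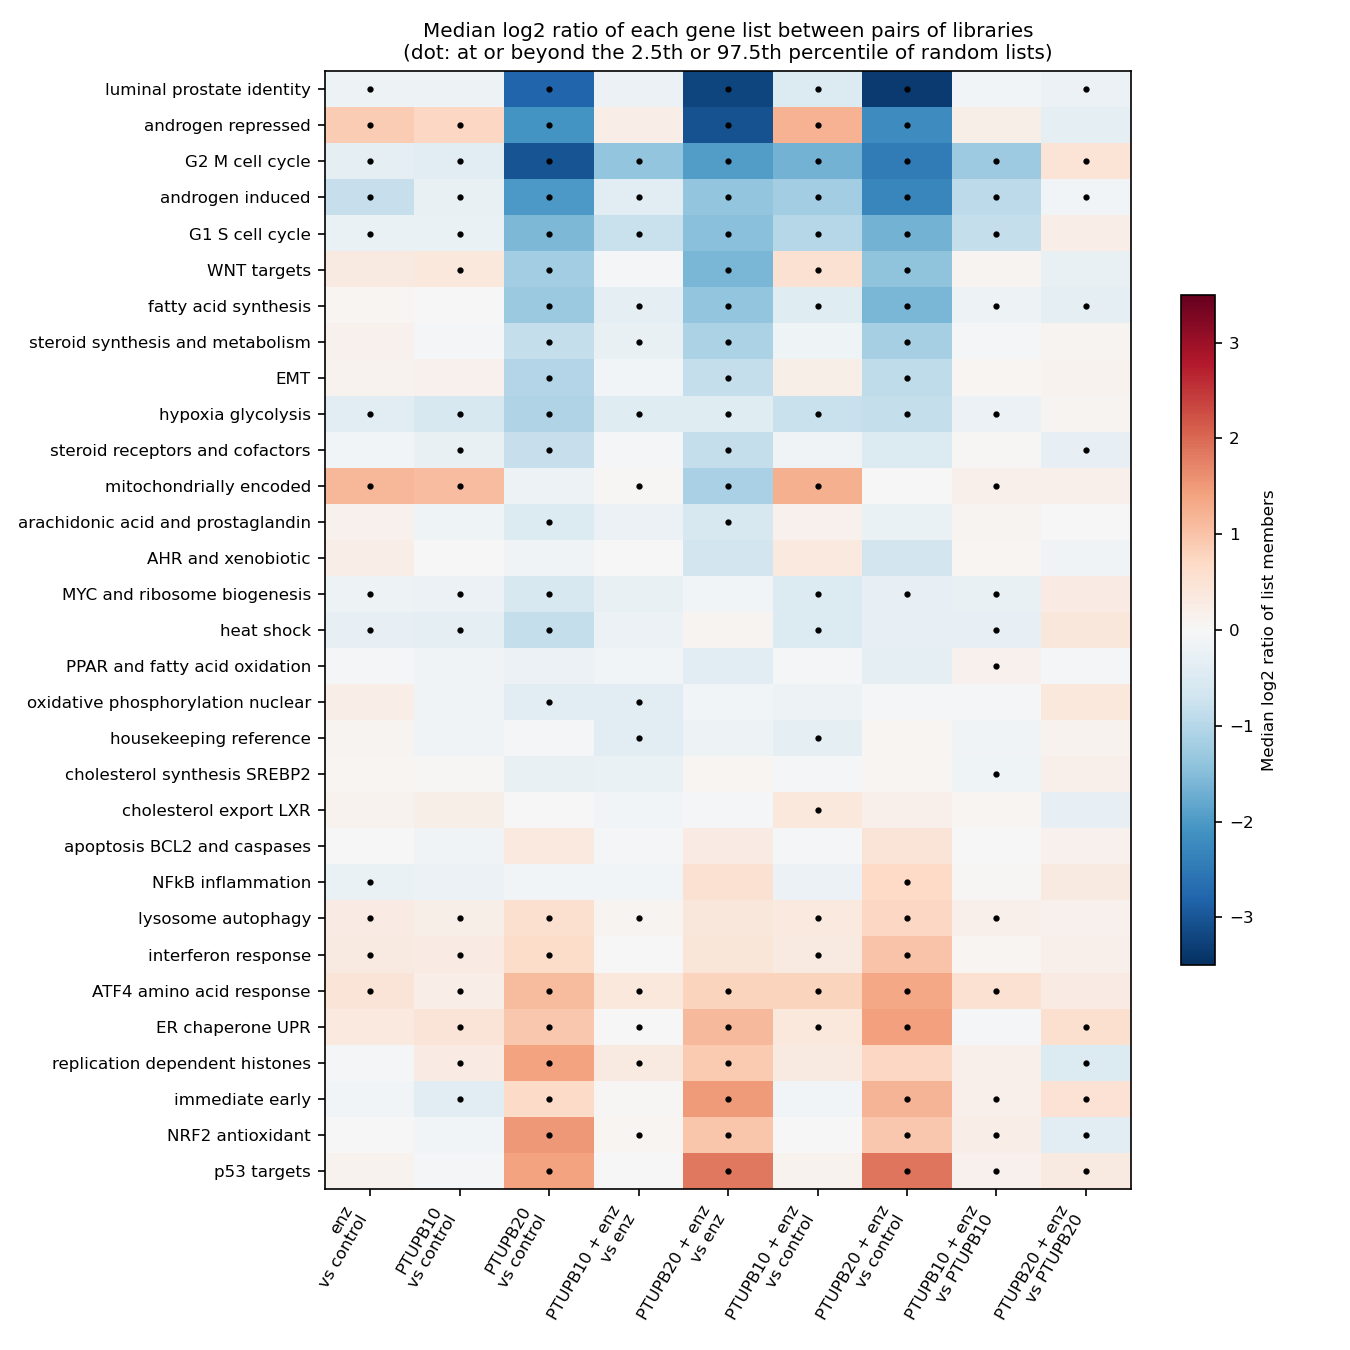
Median log2 ratio of each gene list in 9 pairs of libraries, with dots where the list lies among the lowest or highest 2.5% of 10000 random lists; some medians near 0 change sign after TPM rescaling, among them the lysosome list with enzalutamide and the lysosome, interferon and ATF4 lists at 10 uM PTUPB.

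Whether the enzalutamide effect changes with PTUPB dose was tested as an interaction with linear dose. No gene passed by limma (0 of 12960; 223 at unadjusted p under 0.05), and limma-voom gave 0 and 92, so synergy or antagonism is not shown for any single gene. FKBP5 came with a positive value (1.18, unadjusted p 0.0037, adjusted p 1), because it was 5.70-fold lower with enzalutamide at 0 uM PTUPB and level at 20 uM. The smallest p-values were in small RNA genes with at most 19 fragments in any library: SNORD53B (2.25, unadjusted p 0.00083), Y_RNA (2.05, 0.0011), MIR378J (2.45, 0.0016), SNORD99 (-1.73, 0.0017) and MIR6719 (-2.00, 0.0018). List medians were positive for androgen-induced (0.37), G2/M (0.42) and heat shock genes (0.38), each at percentile 100, and negative for mitochondrially encoded (-0.48) and androgen-repressed genes (-0.59), each at percentile 0. Enzalutamide pair medians at 0, 10 and 20 uM PTUPB were -0.35, -1.27 and 0.47 for G2/M genes. For androgen-induced genes they were -0.81, -0.92 and -0.10. A line in dose cannot show the lower value at 10 uM. With 1 library per cell, a gene that bottoms out at 20 uM gives the same positive value as antagonism.

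**Figure D4:**
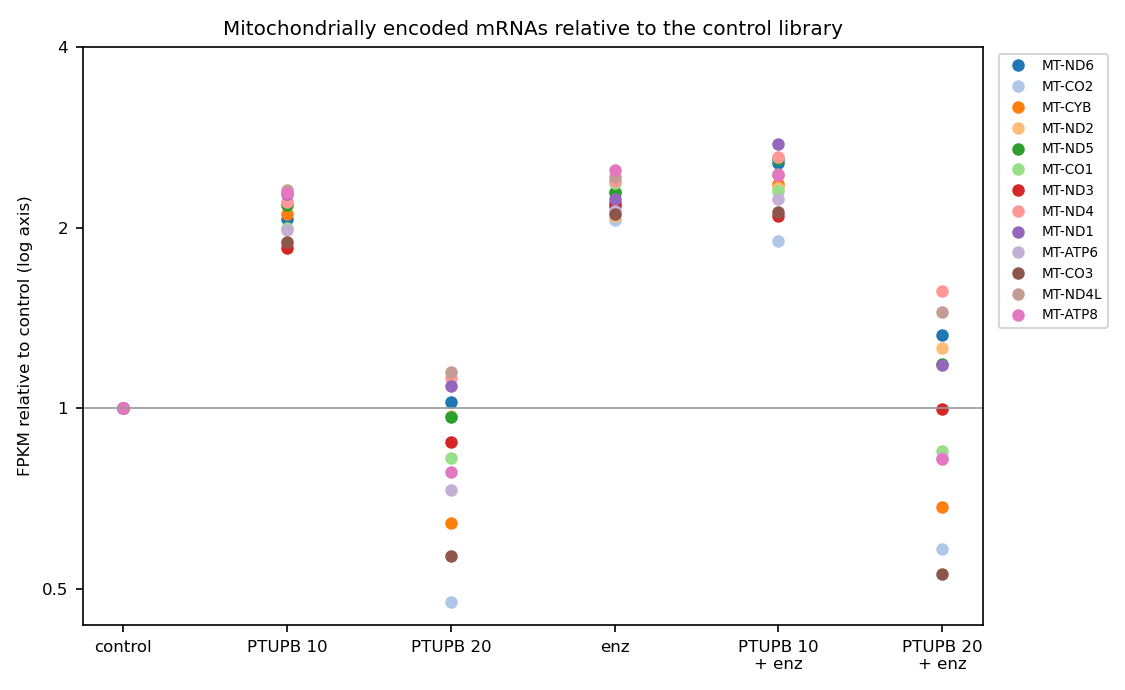
FPKM of the 13 mitochondrially encoded mRNAs in each library relative to control, higher with enzalutamide or 10 uM PTUPB and spread around 1 at 20 uM.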

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

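No paired analysis was possible because there is 1 library per group and the labels name no replicate or batch; pairs matched by dose stand in for it. Pair counts and model calls were recomputed with pseudocount 0.1, with no filter on low values, with mean FPKM of at least 5, and after rescaling to TPM, by total fragments or by median of ratios. Model calls were also recomputed without trend and with limma-voom, and those of the additive model without each library in turn. Fewer genes are counted at mean FPKM of at least 5 by construction; for the other settings the cause was not tested. Genes at log2 1 or more in pairs with pseudocount 0.1, no filter, mean FPKM of at least 5 and TPM numbered 742, 744, 111 and 792 for enzalutamide against control (348 as reported), 633, 747, 74 and 569 for 10 uM PTUPB against control (310), 990, 958, 148 and 820 for the 10 uM combination against enzalutamide (494), 1231, 1142, 311 and 1324 for it against control (686), 854, 966, 146 and 720 for it against 10 uM PTUPB (443), and 1816, 1606, 308 and 1857 for the 20 uM combination against 20 uM PTUPB (873). At mean FPKM of at least 5 they were 1589 for 20 uM PTUPB against control (2867), 2211 for the 20 uM combination against enzalutamide (3799) and 2162 for it against control (3758).

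The additive enzalutamide effect, 0 genes as reported, gave 9 genes after TPM and 1 with limma-voom. A count without a test, of genes at log2 1 or more in every matched pair, gave 9 for enzalutamide and 1931 for 20 uM PTUPB. The 20 uM PTUPB effect gave 1201 with no filter and from 324 (without enzalutamide) through 982 (without control) to 5403 (without 20 uM PTUPB) with 1 library left out. The contrast of 20 against 10 uM gave 868 with no filter and from 838 (without 10 uM PTUPB) through 1139 (without 10 uM PTUPB plus enzalutamide) to 5591 (without 20 uM PTUPB). Genes of the 20 uM combination beyond control and both agents, 256 higher and 131 lower, gave on the higher side 482 with no filter, 106 at mean FPKM of at least 5, 165 after TPM and 140 by total fragments, and on the lower side 600 with pseudocount 0.1, 41 at mean FPKM of at least 5, 654 after TPM and 208 by total fragments.

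Some list medians turned in sign. TPM also moved the median of all genes, to -0.41 for enzalutamide and -0.33 for 10 uM PTUPB, both against control. A turn to a negative value after TPM therefore does not by itself place a list below most genes. After TPM, ATF4 genes stood at -0.081 and interferon genes at -0.022 at 10 uM PTUPB against control, interferon genes at -0.01 in the 10 uM combination against control, lysosome genes at -0.106 with enzalutamide, -0.102 at 10 uM PTUPB and -0.067 in the additive enzalutamide effect, and NF-kB genes at -0.022 in that effect. Endoplasmic reticulum genes in the 10 uM combination against enzalutamide turned to 0.069 after TPM and 0.098 by total fragments. NRF2 genes at mean FPKM of at least 5 turned to -0.043 in that pair and to 0.004 in the additive enzalutamide effect.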

Other observations

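The glycolysis genes PGK1 and ENO1 were lower in every treated library than in control. PGK1 stood at 195 FPKM in control against 94.2 with enzalutamide, 76.8 and 49.6 at 10 and 20 uM PTUPB, and 52.1 and 52.7 in the combinations; ENO1 stood at 313 against 199, 175, 127, 130 and 165. SCG2, a secretory granule gene, was present at 4.81 FPKM in control and at most 0.218 in every treated library, and VIM stood at 11.9 against 3.96 with enzalutamide. These genes were picked after values were seen. All such differences share 1 control library.

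The mitochondrial ribosomal RNA MT-RNR2 and the mRNA MT-CO1 differed in the combinations. MT-RNR2 held 2.956% of fragments in the 20 uM combination and 2.852% in the 10 uM combination, whereas MT-CO1 held 1.165% and 3.585%. Without enzalutamide both were lower at 20 than at 10 uM PTUPB, MT-RNR2 at 1.776% against 2.744% and MT-CO1 at 1.321% against 3.099%. HSPA5 alone held 2.44% of fragments at 20 uM PTUPB and 3.70% in the 20 uM combination. PLA2G2A was higher with enzalutamide and all but absent at 20 uM PTUPB (29.3 and 0.377 FPKM, with 6.47 in control).

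Of the tests in this part, thinning and the length bins for 20 uM PTUPB and thinning for G2/M genes were set before their own results were seen, though after the calls they examine; the share of falling genes, all mitochondrial tests, the scaling test for G2/M genes and the splits were chosen only after the result was seen.

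The breadth of the 20 uM PTUPB response could come from smaller libraries, from a shift with transcript length or from a few abundant transcripts drawing fragments from the rest. After thinning all libraries to the smallest, 4394 genes passed, close to the 4426 at full depth, and after removing the median shift of 20 length bins per library 4588 passed, so neither accounts for it. Scaled by total fragments, which does not centre the genes, 57.7% of the called genes fell. Dilution by HSPA5 and other abundant transcripts would lower genes, so it does not account for those that rose. The top 10 genes held 6.89% of fragments in control and 8.93% at 20 uM PTUPB. They held 11.69% with enzalutamide and 11.45% in the 20 uM combination. With shares this close, the share of falling genes could hardly have shown dilution and decides nothing for the genes that fell. A general response to toxicity at this dose remains possible and was not tested.

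Mitochondrially encoded mRNAs above control with enzalutamide, 10 uM PTUPB or both could reflect scaling or a control library that stands apart. The smallest list median over these 3 pairs and 3 scalings was 0.727, so scaling does not account for it. The list stood at 0.175 in the 10 uM combination against 10 uM PTUPB, which a shared response and an unusual control library would both give. Both 20 uM libraries lay near control (-0.187 and -0.005), and so below the other treated libraries (-1.14 for the 20 uM combination against enzalutamide), which leaves both open. With 1 control library these cannot be told apart.

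G2/M genes in the 10 uM combination lay below both single agents, which could come from library size or scaling. After thinning the median against 10 uM PTUPB was -1.278, and the highest median over both pairs and 3 scalings was -1.261, so neither accounts for it. A difference in confluence or cell number between single cultures would look the same and was not measured here.

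For the additive enzalutamide effect, the real grouping called 0 genes and so did all 10 splits of the libraries (highest other 0). With 0 genes called by the real grouping, every split calls at least as many, so this comparison could not decide anything. The 10 splits are also too few for a share under 0.05.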
